A study of Mus musculus with 9 samples.

How the data were processed

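RNA-seq libraries of mouse embryonic stem cells were analysed in 3 groups of 3, named here control, Taz KO and Yap/Taz double KO after the sample titles. Control cells carried floxed alleles of Yap and Taz. The sample descriptions give Taz KO cells as deleted for Taz with Yap still floxed, and double KO cells as deleted for both. For the double KO libraries the genotype field names the same genotype as for Taz KO, so the grouping follows the titles and descriptions, which match each other. Per the labels' protocols, cells were kept on fibronectin in N2B27 medium with Lif at 4 ng/ml and the MEK and GSK3 inhibitors PD0325901 (0.4 µM) and CHIR99021 (3 µM), a condition known as 2i/Lif. A Cre-ERT2 transgene was delivered by piggyBac transposition, and recombination was induced with 500 nM of the tamoxifen metabolite 4-OHT. The labels do not say whether the control cells received it. Libraries were made from 1 µg of total RNA with an RNA integrity number above 7 by poly(A) selection and a directional kit, and were sequenced on a NextSeq 500 for 75 cycles.

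The deposited table holds an FPKM value (fragments per kilobase, scaled by sequencing depth) per gene and library, made by the authors. The submitters' processing notes name TopHat2 2.1.1, HTSeq 0.6.1, DESeq2 and the mouse genome build mm10, without saying what each was used for. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies may therefore be split between them. The table has 38940 genes, of which 24621 were above 0 in at least 1 library, and every column belonged to a sample analysed here.

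Within a gene, the deposited FPKM values were whole multiples of what 1 read is worth, within a tolerance of 0.001, for 24619 of the 24621 genes. This gave the reads behind each value. Recovered totals were 23.5, 21.0 and 19.5 M reads for control replicates 1, 2 and 3, 22.0, 21.5 and 18.7 M reads for Taz KO, and 21.1, 21.5 and 18.9 M reads for double KO. The worth of 1 read varied between libraries as the inverse of a median-of-ratios size factor of the gene counts, with a largest deviation of 0.00937%. The columns were therefore already on a common scale set by the typical gene and not by the library total. The recovered reads are the smallest whole numbers that fit and could be too low by a common factor for a gene whose reads share a divisor. Poly(A) selection and gene length affect an FPKM value, so comparisons were made within genes. Equal poly(A) selection in all 9 libraries was assumed and not tested.

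Differences between groups were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5). The 11674 genes with a mean FPKM of at least 1 over the 9 libraries entered the test. A model of group means was fitted to all 9 libraries (6 residual degrees of freedom), with moderated variances that followed a trend in the mean. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and an adjusted p under 0.05 was the threshold. All adjusted p-values of genes come from this limma test, and log2 fold changes are on the log2(FPKM + 0.5) scale, which understates the change of genes with low values. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. No pair of replicates agreed within sampling noise: a chi-square test of the recovered reads gave 5.46 to 43.8 per gene over pairs within a group, so all 9 libraries were counted.

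Libraries with the same replicate number in the titles tended to deviate together, less clearly for number 1. Deviations from the group means correlated at 0.192 to 0.711 in the 9 pairs of libraries with the same number and at -0.688 to 0.394 in the 18 pairs with different numbers. Double KO 1 correlated at 0.192 with control 1 and at 0.274 with control 3. Deviations cancel within a group, so the negative values partly follow from the positive ones. The pairing comes from the values, since the labels give the number without saying what it marks. The fit with the replicate number as a block is therefore printed beside a gene or list whose call it changed, and beside the rises or falls counted in a comparison or list where it moved either by over 1.5 times.

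The lists fixed for testing numbered 28. They were YAP/TAZ target genes, Hippo pathway and TEAD partners, naive pluripotency, general pluripotency, formative and primed pluripotency, primitive endoderm, trophectoderm, mesoderm and primitive streak, neuroectoderm, germline, 2-cell-like state, and fibroblast and mesenchyme. The others were actin cytoskeleton and focal adhesion, p53 target genes, apoptosis regulators, cell cycle, Wnt/beta-catenin targets, LIF/STAT3 targets, FGF/ERK targets, BMP and TGF-beta/Nodal targets, glycolysis, cholesterol biosynthesis, imprinted genes, interferon response, integrated stress response, sex-linked library check, mitochondrially encoded transcripts and replication-dependent histones. Lists with at least 3 tested members (27 lists) were tested with limma's camera at a preset correlation of 0.01 on the same fit, which compares a list with all other tested genes. Camera p-values were adjusted over the 27 lists and 3 comparisons together. Zscan4a, Dux and Kcnq1ot1 of these lists were not analysed here.

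The genes named in the text follow a fixed rule: the targeted genes Wwtr1 (the Hippo effector TAZ) and Yap1; in each comparison the 12 largest rises and 12 largest falls among called genes whose groups of values do not overlap, leaving out predicted genes and pseudogenes; up to 4 called members of each list with the largest changes; and Cyr61, Ctgf, Ankrd1, Tead4, Pou5f1, Sox2, Nanog, Klf4, Esrrb and Cdx2. Not all genes that this rule selects are reported here. The gene listed in the table as Taz is tafazzin and was not taken for the Hippo effector. Positions are those of GENCODE M21 on GRCm38 (the assembly also called mm10), matched by symbol for 37333 genes of the table, 1751 of them through an older symbol.

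Both knockout groups were compared with the same 3 controls. The correlation and covariance of their log2 fold changes were therefore set beside values from 100 simulated draws of unchanged groups. In these draws the controls were simulated too and shared by both comparisons. Libraries were independent or, chosen after the data were seen, correlated within the same number as their deviations were. Genes were drawn independently of each other. Alternatives covered the pseudocount (1 and 0.1), the filter (none, and a mean FPKM of at least 5), rescaling, quantile normalization, the replicate block, fits of only the 2 groups compared, library weights (limma's arrayWeights), a fold minimum, an estimated correlation and limma's fry for the lists, and leaving out each library in turn. Fits with limma's voom on the recovered whole reads, without the replicate-2 libraries, and without the genes of chromosomes 6, 8, 14 and Y were added after the data were seen. The pipeline was tested on simulated data with known changes. The tests recovered 40.8% of genes changed 1.5-fold, 76% of those changed 2-fold and 95.9% of those changed 4-fold for double KO against control (11687 simulated genes tested). The same shares were 51.0%, 76% and 97.9% for Taz KO against control, and 50%, 83% and 97.9% for double KO against Taz KO. The simulation changed 200 genes in each knockout group and drew libraries without the pairing by number. The shares therefore need not hold for comparisons in which many more genes change. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.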

Results

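The study asked what the Hippo pathway effectors YAP and TAZ do in mouse embryonic stem cells. YAP and TAZ are co-activators that bind TEAD transcription factors. RNA-seq profiles of 3 control, 3 Taz KO and 3 Yap/Taz double KO libraries were compared, with 18.7 to 23.5 M recovered reads per library and 11674 genes tested. A group's value is the mean FPKM ± SD over its 3 libraries (n = 3) unless stated otherwise.

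The targeted genes were examined first. Yap1 (ENSMUSG00000053110; chromosome 9, 7931999 to 8004596 on GRCm38) was at 18.4 ± 0.573 FPKM in control, 18.3 ± 0.346 in Taz KO and 4.25 ± 0.334 in double KO, which was 23.0% of control. All 3 double KO libraries lay below all others, with a log2 fold change of -1.998 (SE 0.07, adjusted p = 3.75e-06) against control and -1.99 (adjusted p = 7.75e-06) against Taz KO. Between Taz KO and control the Yap1 log2 fold change was -0.01 (adjusted p = 0.992). Wwtr1, which encodes TAZ (ENSMUSG00000027803; chromosome 3, 57455649 to 57575910), was at 12.1 ± 0.847 FPKM in control, 10.8 ± 1.58 in Taz KO and 13.9 ± 0.772 in double KO. Its adjusted p was 0.684 for Taz KO against control, 0.22 for double KO against control and 0.0657 for double KO against Taz KO, where the fit with the replicate block gave 0.0191. The summed value of a gene cannot show the loss of a single exon, and the labels do not give the deleted exons, so Wwtr1 does not check the deletion of Taz in either knockout group. The groups are therefore those named by the labels.

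**Figure D1:**
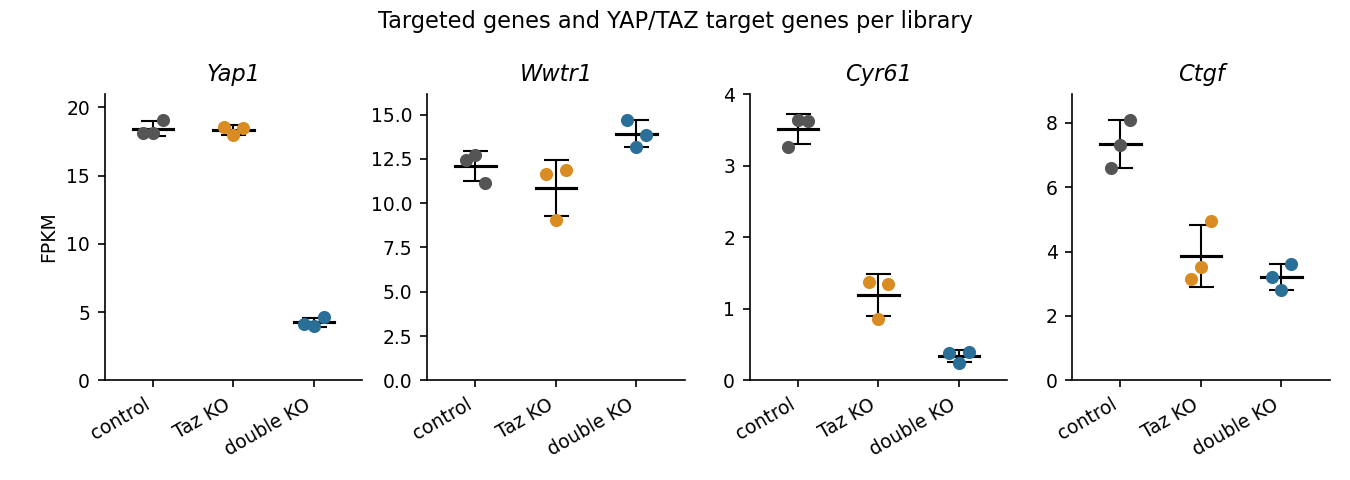
FPKM of Yap1, Wwtr1, Cyr61 and Ctgf (vertical axes, each from 0) in the libraries labelled control, Taz KO and double KO, with 1 point per library and lines for the group mean and 1 SD either side. Yap1 was at 4.25 FPKM in double KO against 18.4 in control, and Cyr61 was lower in Taz KO (1.19) and double KO (0.344) than in control (3.52).

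The comparison of double KO with control addresses the loss of both factors by the labels. Genes of chromosomes 8, 6, 14 and Y also differed from control in both knockout groups, as described below. Other differences between these cells and control therefore cannot be told apart from the loss of both factors. The known YAP/TAZ targets Cyr61 and Ctgf, which encode secreted matricellular proteins, fell: Cyr61 (chromosome 3, 145646976 to 145649981) from 3.52 ± 0.215 to 0.344 ± 0.0848 FPKM and Ctgf from 7.33 ± 0.752 to 3.21 ± 0.391, with adjusted p = 9.38e-05 and 0.00197. The largest fall on the log2(FPKM + 0.5) scale (-3.78) was that of Mme, which encodes the membrane metalloendopeptidase neprilysin, from 19.4 ± 2.6 to 0.955 ± 0.293 FPKM. Krtdap, a gene of keratinocyte differentiation, had the largest rise on that scale (3.46), from 0.233 ± 0.0395 to 7.79 ± 2.16 FPKM, and the AP-1 subunit gene Jun rose from 2.11 ± 0.643 to 21.4 ± 4.60 FPKM. In all, 1443 genes rose and 1505 fell, 25.3% of those tested, and 204 rises and 207 falls were at least 2-fold. The values of the groups did not overlap for 2941 of these 2948 genes, and for 45.6% of all tested genes where chance gives 10%. With the replicate block 2828 genes rose and 3284 fell. Of the 1443 rises without the block, 244 lay on chromosome 8, 145 on chromosome 6 and 73 on chromosome 14. These chromosomes held 668, 522 and 397 of the 11674 tested genes. Among rises named for this comparison, Gpnmb, Plbd1, Cdkn1b, Gata2 and Peg10 lie on chromosome 6. Klf2, Junb, Nanos3 and Bst2 lie on chromosome 8, and Scara5 and Tnfrsf10b on chromosome 14. The count of 2948 became 1505 without control 1, 1921 without control 3 and 1830 without double KO 3. Of 112 named calls, 80 stayed under an adjusted p of 0.05 in all 9 fits without 1 library. Calls lost numbered 29 without control 1, 15 without control 2, 23 without control 3, 7 without Taz KO 1, 3 without Taz KO 3, 19 without double KO 1, 12 without double KO 2 and 26 without double KO 3.

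Among the other genes named in double KO against control, Cth (chromosome 3, 157894248 to 157925077), the enzyme that makes cysteine from cystathionine, fell from 75.3 ± 4.60 to 9.74 ± 0.786 FPKM (log2 fold change -2.89, SE 0.15, adjusted p = 2.42e-05). The adhesion gene Bcam fell from 66.2 ± 7.10 to 8.45 ± 2.15 FPKM, and Dnmt3l, a cofactor of de novo DNA methylation, from 82.6 ± 11.9 to 12.3 ± 3.10. Log2 fold changes were -3.38 for Accsl, -3.06 for the transglutaminase gene Tgm1, -2.82 for Ddah1, -2.58 for the BMP target Id2 and -2.41 for Igfbp2. Among rises, log2 fold changes were 2.96 for S100a14, 2.68 for the ferritin receptor gene Scara5, 2.51 for Lrrc15, 2.47 for Plbd1, 2.31 for the water channel gene Aqp3, 2.28 for Lgals9 and 2.13 for S100a6. Gpnmb rose by 3.04 on the log2 scale with a wide spread in double KO, 17.1 ± 11.5 FPKM. The adjusted p-values of all genes in this paragraph lay between 3.75e-06 and 0.00218, and each stayed under 0.05 in all 9 fits without 1 library.

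Pluripotency genes did not move as a block in double KO. Of 20 naive pluripotency genes 5 rose and 6 fell over all genes tested, and 6 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.982). Dppa5a (log2 fold change -1.52, adjusted p = 5.2e-05) and Klf4 (-0.72, 0.0146) fell, and Klf2 (0.86, 0.000539), which lies on chromosome 8, rose. Of 15 general pluripotency genes 1 rose and 5 fell, and 1 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.0709, 0.0358 with the replicate block, and adjusted p = 0.874 with the block and an estimated correlation). Trim28 fell by 0.66 and Sox2 by 0.33 on the log2 scale (adjusted p = 0.0173 and 0.0148), and Nanog fell by 0.31 (adjusted p = 0.0463). Pou5f1 was at 455 ± 30.9 FPKM in control and 399 ± 58.2 in double KO (adjusted p = 0.33, and 0.0239 with the replicate block), and Esrrb at 130 ± 11.2 and 135 ± 5.19 (adjusted p = 0.702). Of 11 formative and primed genes 3 fell, also adjusted over the list alone, with Foxd3 at -1.84, Pou3f1 at -0.91 and Dnmt3b at -0.61 on the log2 scale (camera adjusted p = 0.873). The calls of Sox2 and Trim28 were lost in 2 of the 9 fits without 1 library and that of Nanog in 7, with the highest adjusted p without control 1 (0.0657, 0.0691 and 0.135). The fit with the replicate block gave 8 rises and 7 falls of naive genes. In it 1 general pluripotency gene rose and 10 fell, and 2 formative and primed genes rose and 3 fell.

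Cholesterol synthesis genes and genes of the integrated stress response, the ATF4 programme, were the lists with the smallest p-values in double KO against control. Other splits of the same 6 libraries, described below, called up to 7 lists by camera where the real split called 6. The number of lists called therefore does not set the real grouping apart. Of 21 cholesterol biosynthesis genes 12 fell and none rose over all genes tested, and 14 fell adjusted over the list alone (camera adjusted p = 1.5e-05). With an estimated correlation the adjusted p was 0.818. Sqle, the squalene epoxidase gene, fell from 33.6 ± 1.70 to 16 ± 3.55 FPKM and Fdps from 146 ± 6.07 to 73.4 ± 17.7, with adjusted p = 0.00346 and 0.00875. Of 16 stress response genes 8 fell and none rose, and 10 fell adjusted over the list alone (camera adjusted p = 5.05e-05, and adjusted p = 0.62 with an estimated correlation). The serine synthesis genes Phgdh and Psat1 had log2 fold changes of -1.27 and -1.25, the glutathione-degrading enzyme gene Chac1 -2.29 and the pseudokinase gene Trib3 -0.83. Of 20 glycolysis genes 5 fell and none rose, and 7 fell adjusted over the list alone, and 14 fell with the replicate block (camera adjusted p = 0.00652). With an estimated correlation the adjusted p was 0.818, and with quantile normalization 0.113. Ldha fell by 0.99 and Eno1 by 0.72 on the log2 scale (adjusted p = 0.0448 and 0.0233). The Ldha call was lost in 7 of the 9 fits without 1 library and that of Eno1 in 3, with the highest adjusted p without control 1 (0.152 and 0.0911).

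Mitochondrially encoded transcripts were higher in double KO. Of 12 tested, 6 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.00652), with mt-Nd6 at 0.53, mt-Cytb at 0.49 and mt-Nd4 at 0.47 on the log2 scale. The list had adjusted p = 0.818 with an estimated correlation, 0.156 with quantile normalization and 0.211 without a filter on low values, and mitochondrial reads were 3.51% to 3.65% of reads in double KO and 2.57% to 3.12% in control. Of 26 cell cycle genes 6 fell and 2 rose, 8 fell and 2 rose adjusted over the list alone, and 19 fell and 2 rose with the replicate block (camera adjusted p = 0.0161, and adjusted p = 0.919 with an estimated correlation). The mitotic cyclin gene Ccnb2 fell by 0.57 on the log2 scale (adjusted p = 0.00827), and the rises were those of Cdkn1b (0.80, adjusted p = 0.0014) and Cdkn2b (0.56, adjusted p = 0.0368), both of which encode inhibitors of cyclin-dependent kinases. The cell cycle list had adjusted p = 0.0933 without double KO 2 and 0.269 with quantile normalization, and the Cdkn2b call was lost in 7 of the 9 fits without 1 library (highest adjusted p = 0.129, without control 1).

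YAP/TAZ targets and Hippo pathway genes moved in both directions in double KO. Of 15 tested YAP/TAZ targets 4 fell and 1 rose over all genes tested, and 4 fell and 2 rose adjusted over the list alone. The list did not pass the camera test, which compares it with all other genes (adjusted p = 0.366). Limma's fry, which asks whether a list moves at all, called it lower (adjusted p = 0.00348). Besides Cyr61 and Ctgf, Amotl2 (log2 fold change -1.62, adjusted p = 0.00189) and Nuak2 (-1.20, 0.00126) fell, while Nt5e, which encodes the ecto-nucleotidase CD73, rose (1.96, 0.0068). Ankrd1 was listed at 0 in all libraries except control 3. Of 23 Hippo pathway genes and TEAD partners 4 rose and 4 fell, and 5 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.817). The scaffold genes Ajuba (-1.24) and Wwc1 (-1.10) fell and Tead2 (0.71) rose, with adjusted p of 0.000578, 8.03e-05 and 0.000295, and Tead4 was at 0.05 (adjusted p = 0.677). Of 26 listed actin cytoskeleton and focal adhesion genes 21 were tested, of which 4 rose and 3 fell, and 5 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.875). In the fit with the replicate block 3 YAP/TAZ targets rose and 4 fell, 7 Hippo pathway genes rose and 5 fell, and 6 actin and focal adhesion genes rose and 5 fell.

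Lineage genes showed no common direction that passed the camera test in double KO against control. Fry called the primitive endoderm list lower (adjusted p = 0.00926) and the trophectoderm (0.0316) and neuroectoderm (0.0331) lists higher. It did not call the mesoderm list (adjusted p = 0.142). Of 10 tested trophectoderm genes 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.126). The rises included Gata2 (1.86 on the log2 scale, adjusted p = 0.0102), Krt8 (0.98, 0.00348) and Tfap2c (0.78, 0.000578), while Cdx2 was below the level tested at 0.206 ± 0.0668 FPKM in control and 0.378 ± 0.320 in double KO. Of 6 primitive endoderm genes 4 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0883). The falls included the basement membrane genes Lamb1 (-1.08), Col4a1 (-0.83) and Sparc (-0.75), with adjusted p of 0.000339, 0.00551 and 0.00216. Of 4 neuroectoderm genes 1 rose and 1 fell, and 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.936). The rise was that of Nes, the gene of the filament protein nestin, at 1.85 (adjusted p = 3.25e-05). Of 4 mesoderm and primitive streak genes limma called 0, also with voom and adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05 (camera adjusted p = 0.673), while 2 rose with the replicate block. With that block 6 trophectoderm genes rose and 2 fell, and 2 neuroectoderm genes rose and 2 fell. The median, the mean and the test of a list differed in sign for naive pluripotency, formative and primed pluripotency, neuroectoderm, germline, Hippo pathway, p53 target, apoptosis and BMP genes.

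**Figure D2:**
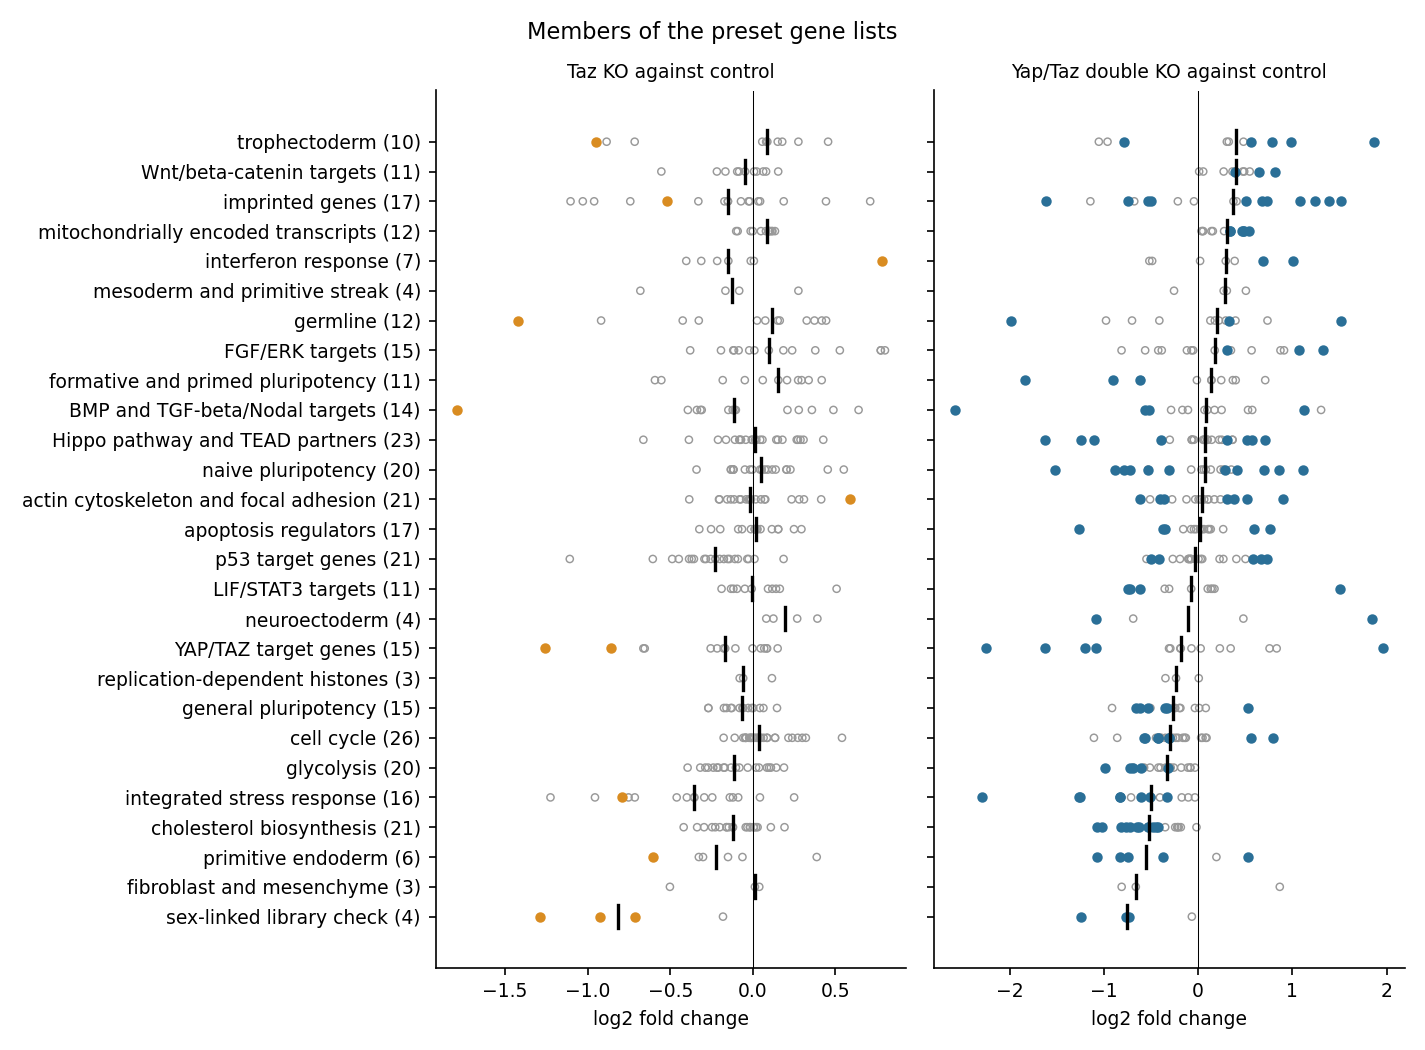
Log2 fold changes of the tested members (points) of each preset list against control in Taz KO and double KO, with filled points for genes with an adjusted p under 0.05, a black bar for the list median and the number of tested members in brackets. In double KO 12 of 21 cholesterol biosynthesis genes and 8 of 16 stress response genes fell, and 6 of 12 mitochondrially encoded transcripts rose.

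The comparison of Taz KO with control addresses the loss of Taz alone by the labels. It gave 84 rises and 66 falls, 1.28% of the genes tested. Genes of chromosomes 8, 6, 14 and Y also differed from control in both knockout groups, as described below. Other differences between these cells and control therefore cannot be told apart from the loss of Taz. The helix-loop-helix regulator gene Id2 (chromosome 12, 25093799 to 25097140) fell from 6.89 ± 0.431 to 1.63 ± 0.0953 FPKM and Accsl from 7.34 ± 1.16 to 1.61 ± 0.338, with adjusted p = 0.000568 and 0.00224. Cyr61 fell from 3.52 ± 0.215 to 1.19 ± 0.290 FPKM (log2 fold change -1.26, SE 0.16, adjusted p = 0.012) and Ctgf from 7.33 ± 0.752 to 3.86 ± 0.954 (-0.86, SE 0.16, adjusted p = 0.0373). The peptide transporter gene Slc15a2 rose from 0.507 ± 0.130 to 2.19 ± 0.226 FPKM (adjusted p = 0.00393), and Tex13 from 0.0533 ± 0.0195 to 2.66 ± 1.23 (adjusted p = 0.012). Of the 83 rises with a known position, 62.7% lay on chromosome 8, which held 5.72% of the tested genes. Without the genes of chromosomes 6, 8, 14 and Y, the fit called 15 rises and 49 falls.

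The other named falls in Taz KO against control included Smoc1 (-2.20 on the log2 scale), the redox gene Glrx (-1.69), the co-stimulatory ligand gene Cd80 (-1.53), the X-linked homeobox gene Rhox5 (-1.42) and Htra1 (-1.12). Rises included S100a14 (1.28), the carboxypeptidase gene Cpe (0.95), the tight junction gene Cldn3 (0.78) and Bst2 (0.78), which encodes the virus-tethering protein tetherin, and Cpe and Bst2 lie on chromosome 8. Their adjusted p-values lay between 0.00962 and 0.0282. At least 2-fold changes numbered 3 rises and 25 falls. All 150 called genes had groups of values that did not overlap, as had 18.7% of all tested genes, where chance gives 10%.

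With the replicate block 908 genes rose and 473 fell in Taz KO against control, so that 65.7% of calls were rises where 56% were without it. The count of 150 became 11 without control 1, 22 without control 2, 84 without control 3, 70 without Taz KO 1, 97 without Taz KO 2, 17 without Taz KO 3, 72 without double KO 1 and 230 without double KO 2. Of the 32 named calls, 4 (Id2, Accsl, Ddx3y and Slc15a2) stayed under an adjusted p of 0.05 in all 9 of these fits. The others lost the call in at least 1 fit: 28 without control 1, 23 without control 2, 9 without control 3, 11 without Taz KO 1, 12 without Taz KO 2, 25 without Taz KO 3, 11 without double KO 1 and 7 without double KO 3. Cyr61, for example, had an adjusted p of 0.0809 without control 1.

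Of the lists, stress response, p53 target and YAP/TAZ target genes were lower in Taz KO than in control by camera at its preset correlation. Limma's fry gave adjusted p = 0.0462, 0.167 and 0.018 for these lists. Another split of the same 6 libraries, described below, also called 7 lists by camera. The number of lists called therefore does not set the real grouping apart. Of 16 stress response genes 1 fell over all genes tested, 4 fell and 1 rose adjusted over the list alone, and 10 fell and 1 rose with the replicate block (camera adjusted p = 1.5e-05, and adjusted p = 0.619 with an estimated correlation). The member called was Trib3, at -0.79 on the log2 scale. Of 21 p53 target genes 0 were called by limma over all genes tested, also with voom, while 4 fell with the replicate block, 3 fell adjusted over the list alone and 8 were lower at an unadjusted p under 0.05. Their median log2 fold change was -0.23 (camera adjusted p = 1.5e-05, and adjusted p = 0.818 with an estimated correlation). Of 15 YAP/TAZ targets Cyr61 and Ctgf fell over all genes tested 3 fell adjusted over the list alone and 4 fell with the replicate block (camera adjusted p = 0.00652, adjusted p = 0.48 with an estimated correlation and 0.304 with a filter at a mean FPKM of 5). Of 20 naive, 15 general, and 11 formative and primed pluripotency genes limma called 0, also with voom and adjusted over each list alone, and 3 naive genes were higher and 1 of each list lower at an unadjusted p under 0.05 (camera adjusted p = 0.722, 0.252 and 0.873). In the fit with the replicate block 2 naive genes rose and 1 fell, 1 general pluripotency gene fell and 2 formative and primed genes rose. Log2 fold changes were -0.13 for Pou5f1, 0.00 for Sox2, 0.07 for Nanog, -0.12 for Klf4 and 0.04 for Esrrb, with adjusted p of 0.873 to 0.996. Tead4 was at 0.31 (adjusted p = 0.134, and 0.0214 with the replicate block). It lies on chromosome 6, whose tested genes had a median of 0.21 in this comparison.

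Smaller list results in Taz KO against control depended on single libraries. Of 14 BMP and TGF-beta/Nodal targets Id2 fell over all genes tested and 3 fell adjusted over the list alone (camera adjusted p = 0.017, and adjusted p = 0.818 with an estimated correlation). Of 17 imprinted genes Zrsr1 fell, at -0.52, and 4 fell adjusted over the list alone (camera adjusted p = 0.0327, and adjusted p = 0.619 with an estimated correlation). Of 6 primitive endoderm genes Lamb1 fell, at -0.61, and 2 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0471, and adjusted p = 0.818 with an estimated correlation). Counts in the fit with the replicate block differed: 2 BMP targets rose and 3 fell, 1 imprinted gene rose and 5 fell, and 1 primitive endoderm gene rose and 1 fell. The adjusted p of the BMP list was 0.298 with the replicate block, 0.0662 with quantile normalization and 0.093 without Taz KO 2. That of the imprinted list was 0.0865 with quantile normalization, 0.157 without control 2 and 0.055 without Taz KO 3. That of the primitive endoderm list was 0.143 with the block, 0.106 with quantile normalization, 0.22 without control 2, 0.0986 without Taz KO 1, 0.157 without Taz KO 3, 0.0502 without double KO 1 and 0.0514 without double KO 3. The median, the mean and the test differed in sign for trophectoderm, germline, fibroblast, actin, apoptosis and LIF/STAT3 genes.

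The genes of chromosomes 8, 6 and 14 were higher by their medians, and the 5 tested genes of the Y chromosome lower, in both knockout groups than in control. Of these 5 genes 3 were called in each group. Over 668 tested genes of chromosome 8 the median log2 fold change was 0.35 in Taz KO and 0.30 in double KO against control, and -0.03 between the knockout groups. In Taz KO against control 93.0% of these genes were above 0. Chromosome 6 had medians of 0.21 and 0.19, and chromosome 14 of 0.10 and 0.11. The 17 other nuclear chromosomes except Y lay between -0.03 and 0.03 in Taz KO and between -0.09 and 0.00 in double KO. The 16 tested genes of the mitochondrial genome had medians of 0.02 and 0.28. Per library, the chromosome 8 median relative to the control mean was -0.11 to 0.12 in control, 0.27 to 0.43 in Taz KO and 0.24 to 0.36 in double KO. Of 4 tested sex-linked genes the Y genes Ddx3y, Eif2s3y and Uty fell in both groups, also adjusted over the list alone, with Ddx3y at 10.3 ± 0.910 FPKM in control, 3.91 ± 0.251 in Taz KO and 4.06 ± 0.199 in double KO. The remaining tested member, the Y gene Kdm5d, was not called. Its libraries were at 0.957 to 1.35 FPKM in control, 0.726 to 1.12 in Taz KO and 0.896 to 1.28 in double KO. The sex-linked list had a camera adjusted p of 8.51e-07 in Taz KO and 0.0105 in double KO, and with an estimated correlation adjusted p = 0.474 and 0.631.

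**Figure D3:**
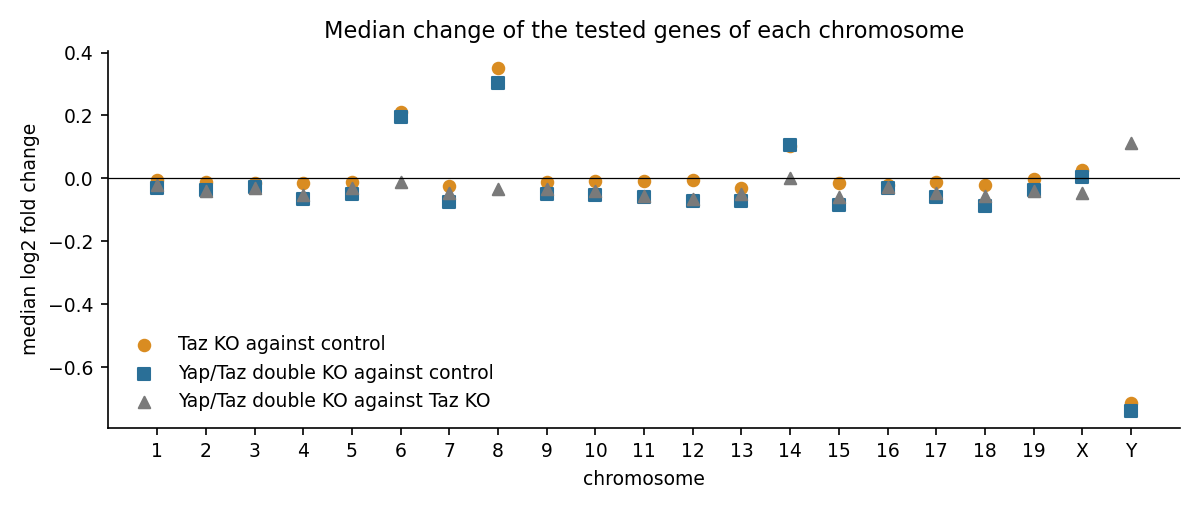
Median log2 fold change of the tested genes of each nuclear chromosome (horizontal axis) for Taz KO against control (circles), double KO against control (squares) and double KO against Taz KO (triangles). Chromosome 8 was at 0.35 and 0.30 against control and the Y chromosome, with 5 tested genes, at -0.71 and -0.74. Between the knockout groups chromosome 8 was at -0.03.

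The comparison of double KO with Taz KO addresses, by the labels, the loss of Yap on top of Taz. It is the direct test of the difference between the knockout groups. Any other differences between the cells of these groups cannot be told apart from the loss of Yap. Jun rose from 1.69 ± 0.770 to 21.4 ± 4.60 FPKM (log2 fold change 3.36, SE 0.27, adjusted p = 0.000475), and the MAP kinase phosphatase gene Dusp10 from 0.525 ± 0.144 to 4.02 ± 0.553. The imprinted gene Peg10, of retrotransposon origin, rose from 2.21 ± 0.475 to 13.5 ± 4.35 FPKM and the galectin gene Lgals1 from 54.5 ± 14 to 189 ± 15.7. Cyr61 fell further, from 1.19 ± 0.290 to 0.344 ± 0.0848 FPKM (adjusted p = 0.00765), while Ctgf was at 3.86 ± 0.954 and 3.21 ± 0.391 (adjusted p = 0.38). Altogether 750 genes rose and 870 fell, 13.9% of those tested, of which 121 and 69 changed at least 2-fold. Groups did not overlap for 1619 of the 1620, and for 30.6% of all tested genes where chance gives 10%. With the replicate block 1963 rose and 2984 fell. The count of 1620 became 1024 without control 1, 482 without Taz KO 1, 2648 without Taz KO 2, 623 without Taz KO 3, 759 without double KO 1 and 627 without double KO 3. Of 88 named calls, 48 stayed under an adjusted p of 0.05 in all 9 fits without 1 library. Calls lost numbered 17 without control 1, 8 without control 2, 13 without control 3, 38 without Taz KO 1, 3 without Taz KO 2, 30 without Taz KO 3, 30 without double KO 1, 11 without double KO 2 and 29 without double KO 3.

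Other falls in double KO against Taz KO were those of Tgm1 (-2.93 on the log2 scale), Mme (-2.85), Bcam (-2.44), Dnmt3l (-2.20), Ddah1 (-2.10), the retinoid-binding protein gene Crabp1 (-1.97), Cth (-1.91) and Fgf17 (-1.85). Rises included Gpnmb (3.13), Krtdap (2.51), Scara5 (2.31), Plbd1 (2.12), Lgals9 (1.99) and the nuclear RNA Neat1 (1.73). Their adjusted p-values lay between 2.97e-05 and 0.00929, and each stayed under 0.05 in all 9 fits without 1 library. Among the fixed pluripotency genes, Sox2 fell by 0.34 (adjusted p = 0.0242), Nanog by 0.38 (0.0333) and Klf4 by 0.60 (0.0442), and Pou5f1 (-0.07) and Esrrb (0.02) were not called (adjusted p = 0.77 and 0.936). Their calls were lost in 4, 7 and 7 of the 9 fits, with the highest adjusted p without Taz KO 1 for Sox2 (0.101) and Nanog (0.125) and without double KO 3 for Klf4 (0.133). Tead4 was at -0.25 (adjusted p = 0.0785, and 0.0156 with the replicate block).

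Cholesterol synthesis and cell cycle genes were lower in double KO than in Taz KO, and p53 target genes, Wnt targets and mitochondrially encoded transcripts were higher. Of 21 cholesterol genes 8 fell, 12 fell adjusted over the list alone, and 14 fell with the replicate block (camera adjusted p = 4.28e-05). Of 26 cell cycle genes 6 fell and 1 rose, 13 fell and 1 rose adjusted over the list alone, and 23 fell and 2 rose with the replicate block (camera adjusted p = 8.8e-05). With an estimated correlation both lists had adjusted p = 0.818. Of 21 p53 target genes 6 rose and 1 fell, also adjusted over the list alone, and 6 rose and 2 fell with the replicate block (camera adjusted p = 0.00859, and adjusted p = 0.853 with an estimated correlation), with the polo-like kinase gene Plk2 at 1.61, Perp at 1.22 and the antiproliferative gene Btg2 at 1.19 (adjusted p = 0.00531, 0.00543 and 0.0037). Against control the p53 list was not called in double KO (median log2 fold change -0.03, camera adjusted p = 0.938). In Taz KO it was lower than in control (median -0.23, camera adjusted p = 1.5e-05). Of 11 Wnt/beta-catenin targets 3 rose, also adjusted over the list alone, and 7 rose with the replicate block (camera adjusted p = 0.0105, and adjusted p = 0.818 with an estimated correlation). These were Cdx1 (0.76), the feedback inhibitor gene Axin2 (0.73) and Fzd7 (0.37), whose calls were lost in 3, 2 and 7 of the 9 fits without 1 library. The highest adjusted p was 0.0807 and 0.0695 without Taz KO 1 for Cdx1 and Axin2, and 0.104 without double KO 3 for Fzd7. The Wnt list had adjusted p = 0.0823 without Taz KO 2. The same 3 Wnt genes rose in double KO against control, also adjusted over the list alone, where 6 rose with the replicate block (camera adjusted p = 0.0558, 0.0358 with the block, and adjusted p = 0.874 with the block and an estimated correlation), and the Fzd7 call there was lost in 3 of the 9 fits (highest adjusted p = 0.0561, without double KO 3).

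Of 12 mitochondrially encoded transcripts 3 rose in double KO against Taz KO, and 4 rose adjusted over the list alone (camera adjusted p = 0.00256, adjusted p = 0.818 with an estimated correlation, 0.0994 with quantile normalization and 0.196 without a filter on low values). Of 10 trophectoderm genes 3 rose, and 4 rose adjusted over the list alone (camera adjusted p = 0.017, and adjusted p = 0.631 with an estimated correlation), with Gata2 at 1.41, Krt8 at 0.83 and Tfap2c at 0.60. The Gata2 and Krt8 calls were lost in 8 and 2 of the 9 fits without 1 library, with the highest adjusted p without Taz KO 1 (0.154 and 0.064). Of 20 glycolysis genes Pdk1 (-0.49) and Ldhb (-0.40) fell, also adjusted over the list alone, and 13 fell with the replicate block (camera adjusted p = 0.0252, and adjusted p = 0.87 with an estimated correlation). The Pdk1 and Ldhb calls were lost in 6 and 2 of the 9 fits (highest adjusted p = 0.139 without Taz KO 1 and 0.0712 without double KO 1). Of 16 stress response genes 6 fell, 7 fell and 1 rose adjusted over the list alone, and 9 fell and 1 rose with the replicate block (camera adjusted p = 0.0496, and adjusted p = 0.818 with an estimated correlation), among them Asns (-0.74), Psat1 (-0.90) and Phgdh (-0.87). The trophectoderm list had adjusted p = 0.0865 with quantile normalization, 0.0698 without Taz KO 3 and 0.164 without double KO 2, and the glycolysis list 0.209 with quantile normalization, 0.0986 without Taz KO 1 and 0.181 without double KO 3. For the stress response list the adjusted p was 0.19 with the replicate block, 0.114 with quantile normalization, 0.0522 without control 2, 0.0852 without Taz KO 1, 0.108 without double KO 1 and 0.0927 without double KO 3. The median, the mean and the test differed in sign for YAP/TAZ target, Hippo pathway, naive pluripotency, neuroectoderm and apoptosis genes.

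The responses of the knockout groups were compared across genes, which are not independent replicates. Of the genes called in Taz KO, 73 rises and 64 falls were also rises and falls in double KO, 91.3% of the Taz KO calls, and 1 gene went in opposite directions. Independent lists of these sizes would share 10.4 rises and 8.51 falls. Shared falls included Id2, Accsl, Cyr61 and Ddx3y, and shared rises Slc15a2 and S100a14. Among these calls from the fit of all genes, 19 shared rises (1.85 for independent lists) and 60 shared falls (8.81) lay outside chromosomes 6, 8, 14 and Y. The separate fit without the genes of these chromosomes gave 15 shared rises and 47 shared falls. Across the 11674 genes the log2 fold changes correlated with Pearson's r = 0.591. Simulated unchanged groups with shared simulated controls gave a median of 0.50 (0.47 to 0.53 over 100 draws) with independent libraries. With libraries of the same number correlated as observed the median was 0.54 (0.4996 to 0.5862). Genes were drawn independently, while the deviations of real libraries are shared across genes, so the simulated ranges may be too narrow. The covariance was 0.0636, against a simulated 0.0155 (0.0141 to 0.0172) with independent libraries and 0.00796 (0.00715 to 0.00923) with correlated ones. The 3 controls are too few to be split, so part of the excess in shared calls may come from the shared controls. Both knockout groups also shared the shifts of chromosomes 8, 6, 14 and Y against control. Other differences from control that their cells share may therefore add to the shared calls. Leaving out the genes of these chromosomes does not remove such differences. Shared rises and falls were 1 and 10 without control 1, 7 and 15 without control 2, and 40 and 36 without control 3.

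**Figure D4:**
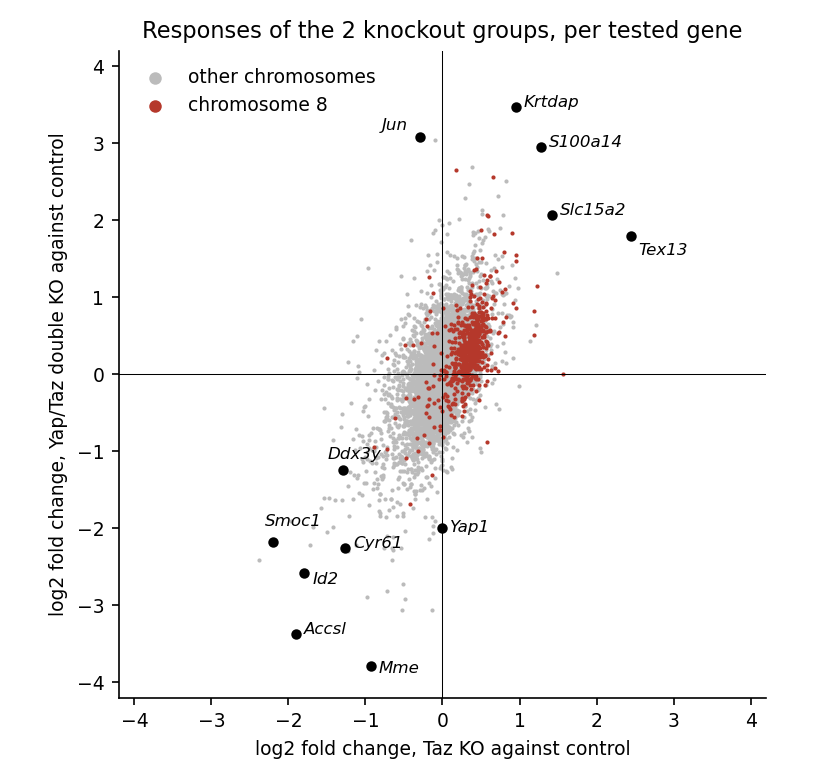
Log2 fold change of each tested gene in Taz KO (horizontal axis) and double KO (vertical axis) against control, with chromosome 8 genes in red and named genes labelled. Yap1 and Jun changed in double KO (-1.998 and 3.08) and were at -0.01 and -0.29 in Taz KO, Cyr61, Id2 and Accsl fell in both, and 93.0% of the chromosome 8 genes lay to the right of 0.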

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

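The choices of test, filter, lists and most alternatives were made before the data were examined; voom on recovered reads, leaving out the 3 replicate-2 libraries, and leaving out the genes of chromosomes 6, 8, 14 and Y were chosen after seeing them. No called list, and no call of a gene named in the text, changed its direction under the alternatives run for it; these left out the other called genes, and for named genes the fits without the replicate-2 libraries and without the genes of chromosomes 6, 8, 14 and Y. Lists without a call could change theirs, as the medians of the LIF/STAT3 and p53 lists did in double KO against control with quantile normalization. Over all alternatives, called named genes kept their call in 3766 comparisons with a setting and lost it in 572, and called lists kept it in 395 and lost it in 84. Uncalled named genes gained a call in 13 and uncalled lists in 38. Of the chromosome medians 149 moved by less than the spread between replicates and 11 by more.

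The counts of called genes, in the order double KO against control (2948), Taz KO against control (150) and double KO against Taz KO (1620), moved with several choices. With the replicate block they were 6112, 1381 and 4947, and all genes called without the block were also called with it. With arrayWeights they were 8636, 4383 and 7439; these fits gave control 1 a weight of 11.5, Taz KO 1 of 4.83 and double KO 1 of 7.85, with 0.147 to 0.739 for the rest, and the weights had not converged, so that they rest mostly on replicate 1. Without the replicate-2 libraries they were 4889, 423 and 4277. Fitting only the 2 groups compared, with fewer degrees of freedom, gave 88 for Taz KO against control and 635 for double KO against Taz KO, and 2824 for double KO against control. Requiring a 2-fold change left 411, 28 and 190. Leaving out single libraries gave 1505 to 3568, 11 to 230 and 482 to 2648, lowest without control 1, control 1 and Taz KO 1. Without the genes of chromosomes 6, 8, 14 and Y, a set that holds fewer genes, Taz KO against control had 64 calls, 15 rises and 49 falls where all genes gave 84 and 66, and double KO against control had 975 rises and 1417 falls where all genes gave 1443 and 1505. Pseudocounts, filters, quantile normalization and voom stayed within 1.5 times of each count (voom 3017, 176 and 1630), and rescaling changed nothing, since the values were already scaled that way, so it says nothing about stability. Apart from fewer genes or libraries, the cause of these shifts was not tested.

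The list tests gave 21 calls, and 0 with an estimated correlation and 11 with quantile normalization, all 11 among the 21. They gave 18 to 25 without single libraries, 21 with the replicate block (18 shared) and 16 with fry (10 shared), which asks whether a list moves at all. Without the genes of chromosomes 6, 8, 14 and Y they gave 16 (15 shared): the sex-linked list had too few members left for the test, and in Taz KO against control the imprinted and primitive endoderm lists had adjusted p = 0.0772 and 0.119, and in double KO against Taz KO the stress response and glycolysis lists 0.476 and 0.119. Without the replicate-2 libraries they gave 20 (17 shared), with 0.0584 for the sex-linked list in double KO against control, 0.384 and 0.121 for the BMP and imprinted lists in Taz KO against control and 0.0738 for the trophectoderm list in double KO against Taz KO. They gave 22 without a filter (18 shared), 14 with a filter at a mean FPKM of 5 (13 shared) and 19 with arrayWeights (17 shared). The block ended the calls of the BMP and primitive endoderm lists in Taz KO against control and of the stress response list in double KO against Taz KO. It added general pluripotency and Wnt targets in double KO against control and imprinted genes in double KO against Taz KO. It added 4 calls of named genes, those of Pou5f1, Tead4 in 2 comparisons and Wwtr1, and changed no other call of a named gene or list. The correlation of the responses was 0.59, and 0.59 to 0.63 without single controls. The planned fits with DESeq2 and edgeR were not run, because the deposited unit is FPKM, and voom was fitted to the recovered reads instead. Depth limits the low genes: Cyr61 rested on 12 to 17 recovered reads per double KO library and 143 to 164 per control library. Of the genes with the smallest change simulated, 2% to 8% were recovered, so small changes without a call are not shown to be absent.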

Other observations

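Members of further lists were called in double KO against control, and none of these lists passed its camera test there. Fry called the BMP list lower (adjusted p = 0.0316) and did not call the imprinted, germline, FGF/ERK and LIF/STAT3 lists. Of 17 imprinted genes 7 rose and 4 fell, and 7 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.74), with the growth inhibitor gene Cdkn1c at 1.51 and Peg10 at 1.38 and the adaptor gene Grb10 at -1.62 on the log2 scale. Against Taz KO 5 imprinted genes rose and 2 fell, and 6 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0669, 0.0487 with the replicate block, and adjusted p = 0.874 with the block and an estimated correlation). Of 12 germline genes 2 rose and 1 fell, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.71), with Nanos3 at 1.51 and Rhox5 at -1.99. Of 15 FGF/ERK targets 3 rose, also adjusted over the list alone (camera adjusted p = 0.444), and the phosphatase gene Dusp5 was at 1.32 and Spry1 at 0.31. Of 11 LIF/STAT3 targets 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.982), with the AP-1 subunit gene Junb at 1.51 and Klf4 at -0.72, and the median of the list was -0.07 and turned to 0.12 with quantile normalization. Of 14 BMP and TGF-beta/Nodal targets 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.817), with Bambi at -0.57. The replicate block gave other counts: 5 germline genes rose and 3 fell, 7 FGF/ERK targets rose and 3 fell, 4 LIF/STAT3 targets rose and 4 fell, and 3 BMP targets rose and 3 fell. Against Taz KO 8 imprinted genes rose and 4 fell with the block.

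Of 21 p53 target genes 3 rose and 2 fell in double KO against control, also adjusted over the list alone (camera adjusted p = 0.938), with Tnfrsf10b, a death receptor gene, at 0.66 and Sesn1 at -0.50. The median of the list was -0.03 and turned to 0.05 with quantile normalization, and 3 rose and 4 fell with the replicate block. Of 17 apoptosis regulators 2 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.982), with Birc3 at 0.76, the death gene Bcl2l11 at 0.59 and the survival gene Bcl2l1 at -0.37. Of 7 interferon response genes 2 rose, 4 rose and 1 fell adjusted over the list alone, and 4 rose and 2 fell with the replicate block (camera adjusted p = 0.266). Bst2 was at 0.68, and B2m, an invariant chain of class I molecules, at 1.01 lost its call in 3 of the 9 fits without 1 library (highest adjusted p = 0.0656, without control 1). Fibroblast genes and replication-dependent histone genes each had 3 tested members, of which limma called 0, also with voom, and 0 were under an unadjusted p of 0.05 (camera adjusted p = 0.936 and 0.85), while 1 fibroblast gene rose and 2 fell with the replicate block. No gene of the 2-cell-like list reached the level tested.

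Tests of copy number and of loss of Taz on chromosome 8, of depth and of a shared day for the replicate-2 libraries, and the 3 tests on Wwtr1 were chosen only after the result was seen. In other splits of the 6 libraries of each comparison, 10 splits are too few for a share under 0.05. Only the real split, 1 of 10, called as many genes in each comparison: 2948, 150 and 1620 genes, with a highest other value of 1, 0 and 0, and also 1, 0 and 0 among the 4 splits that part all numbered pairs. For the lists, 3, 2 and 1 of the 10 splits called as many as the real 6, 7 and 8, with a highest other value of 7, 7 and 6, and 5, 7 and 6 among the splits that part all pairs.

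Genes of chromosome 8 were higher in both knockout groups than in control. A few strongly regulated genes do not account for it, since 93.0% of the 668 tested genes were above 0 in Taz KO against control. The median without the called genes was 0.34 there. Leaving out 52 of 668 genes could hardly move it, so that test adds no support. A bias of GC content, gene length or expression does not account for the shift either, since matched genes of other chromosomes had a median of -0.019. A copy number gain of the whole chromosome, carried by part or all of the knockout cells, may account for it: 100% of the 25 windows of 5 Mb had a median over 0.1, between 0.29 and 0.47. Gain of chromosome 8 is a known change of cultured mouse embryonic stem cells. Loss of Taz itself cannot be told apart from it, because both knockout groups lack Taz by their labels and chromosome 8 differed by a median of -0.034 between them.

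The 3 replicate-2 libraries, 1 of each group, deviated together from their group means: 66.3% of genes had 3 deviations of the same sign, where chance gives 25%. GC content and gene length explained 3.83% of the variance of this deviation, which argues against both. A difference in depth is argued against as the whole cause, since in 3 of 3 groups the libraries closest in depth differed more (chi-square per gene of 24.2 in control, 40.7 in Taz KO and 34.7 in double KO) than replicates 1 and 3 (9.73, 6.54 and 5.46), which were further apart in depth. A shared day of culture, extraction or library preparation is a candidate explanation, with a lowest correlation of 0.192 between libraries of the same number, but it cannot be told apart from other causes because the labels give no dates. No biological explanation was tested.

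Wwtr1 was not called as lower in either knockout group. A swap of Taz KO with control libraries is argued against by Cyr61, which was under the lowest control in 3 of 3 Taz KO libraries. The fall of Cyr61 was already known when this test was chosen, and it cannot show that Taz was deleted. Whether cells of the control genotype were left in the Taz KO libraries was not settled. Cyr61 was at 33.9% of control and Wwtr1 at 74.7% to 98.2% per library. But Cyr61 may also differ between these cells and control for reasons other than the loss of Taz. A deletion that leaves most of the transcript in place may account for the mean Wwtr1 level of 89.7% of control, but it cannot be told apart from other causes without values per exon, which were not analysed here.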
